A study of Mus musculus with 6 samples.

How the data were processed

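RNA was sequenced from 6 samples of the mouse line SVEC4-10, 3 labelled untreated and 3 labelled as treated with nattokinase for 24 hours, and groups and replicate numbers were taken from the sample titles. Total RNA was extracted and libraries were made with a standard Illumina procedure, per the labels' protocols, and neither poly(A) selection nor rRNA depletion nor strandedness is stated there. Per the submitters' processing notes, the tools named are CASAVA, FastQC, MultiQC, Trimmomatic 0.38, HISAT2 2.1.0, featureCounts 1.6.0 and DESeq2 1.22.1, with no role or order given. Those notes name the genome build GRCh38, a human build, whereas the deposited gene identifiers are from mouse.

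The authors deposited 1 file per sample, each with 1 column of values for 55536 Ensembl genes, zeros included, and no filter or pooling was seen in the values. The unit of the deposited values is FPKM, as found from the values themselves. All 55536 identifiers matched GENCODE M21 (GRCm38), and each value multiplied by the length of the gene's merged exons in that annotation was a whole multiple of 1 step per library, within 0.05 of a whole number for 100% of values above 0. The steps give the number of reads or fragments assigned to genes, between 15044778 and 18341370 per library, and which of the 2 was counted is not stated. For a gene with 2 kb of exons, 3 reads correspond to 0.082 to 0.10 FPKM, and limits of this kind cover counting error only. The files held 0 columns of other samples. Coordinates and gene names come from GENCODE M21.

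A test on counts had been planned before the data were examined and was replaced, as the plan foresaw, because the deposited values are FPKM. Values were analysed as log2(FPKM + 1) for genes with at least 1 FPKM in at least 3 libraries, with limma 3.58.1 in R 4.3.3 (a linear model on group, moderated with an intensity trend and robust prior), two-sided, and Benjamini-Hochberg adjustment over the 10913 genes tested at 0.05. A log2 fold change is on this log2(FPKM + 1) scale, which understates the change of low genes, and a fold is the ratio of mean FPKM. Every adjusted p for a gene is from this limma test. A total of 27 gene lists, fixed before the data were examined, were tested with limma's camera at the preset correlation of 0.01, adjusted over the lists, and with camera at an estimated correlation and fry beside it. List members were counted by the gene-wise limma test over all genes and adjusted over the list alone.

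The genes named in the text follow a rule fixed before the data were examined. In each direction it takes the 12 genes with the largest log2 fold change among those past the threshold with a log2 mean CPM of at least 1 and separated groups, leaving out predicted or unnamed genes. In each list it takes up to 4 tested members with the smallest p. Some genes that the rule takes are not reported here. It always includes Srf, Thbs1, Plat, Plau, Vcam1, Icam1, Ccl2 and Nos3. Genes named outside the rule are said to have been chosen after their values were seen.

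The scripts were tested on simulated libraries with 200 changed genes among 10900. The test recovered 61.2% of genes changed 1.25-fold, 90.0% at 1.5-fold, 94.0% at 2-fold and 100% at 3-fold. Of 184 calls 14 (7.61%) were false. Simulated genes of similar level were given the same spread between replicates, so these rates may not hold for the real libraries. Of 27 unchanged lists 0 were called. Their genes were drawn at random and simulated independently, so this could not show false calls that come from correlated members. Genes changed 2-fold had a median absolute log2 fold change of 0.89. Replicates were compared before averaging. Within groups the correlation of log2 values was 0.992 to 0.995. The chi-square per gene between 2 libraries of a group had a median of 0.92 to 1.87 and a mean of 2.50 to 11.5. Counting error alone gives a mean near 1, so the replicates differed by more than that. The first principal component (42.1% of variance) separated the groups, and the second (20.3%) set control replicate 1 apart.

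Some values carry known uncertainty. Exons of 35.7% of the tested genes overlap those of another gene, and without stated strand use the reads of such pairs cannot be told apart. Among named genes this holds for Ccn2, Thbs1, Spp1, Tgm2, Hist1h1e, Tagln, Dusp1, Vcam1, Tap1, Scd2, Col3a1, Ltbp2, Tgfb2, Mcam, Cd9, Cdc20, Car9, mt-Nd2, Edn1, Lpcat3, Pltp, H1f0 and CT010467.1. Acta2 and Actg2 have near-identical paralogs, as do histone genes, and their values are uncertain to that extent. Alternatives planned before the data were examined were limma-voom on the recovered reads, median-of-ratios scaling, other filters, a test against a 1.5-fold change, the replicate number as a block, and leaving out each library in turn. Pseudocounts of 0.1 and 0.5, quantile normalization, protein-coding totals, and a correction for gene length and GC content were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6).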

Results

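Transcript levels were measured by RNA sequencing in SVEC4-10 cells, an immortalised mouse line labelled as endothelial. One group of 3 libraries came from untreated cells and the other group of 3 from cells exposed for 24 hours to nattokinase, a fibrin-degrading serine protease made by Bacillus subtilis during the fermentation of soybeans. The dose is not given in the sources used here. The comparison asks which transcripts differ after the exposure. Each library listed 55536 genes as FPKM, and the reads behind these values were 16208887, 15044778 and 16496433 in the control libraries and 18036428, 17525090 and 18341370 in the nattokinase libraries. Between 18473 and 19391 genes had at least 1 read per library. No label says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

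The cells of all 6 libraries carried abundant collagen transcripts, almost no transcripts of 12 common endothelial genes, and measurable transcripts of some other endothelial and lymphatic genes. The genes of this paragraph were chosen after their values were seen. Over the 6 libraries the mean level of Col1a1, the chain of type I collagen, was 1319 ± 103 FPKM (SD, n = 6), that of Col1a2 was 517 ± 14.4 FPKM and that of Pdgfrb, a receptor of mural cells and fibroblasts, was 18.2 ± 1.77 FPKM. Pecam1, which encodes the endothelial adhesion molecule CD31, had between 0 and 3 reads per library, and Cdh5, which encodes VE-cadherin, had 0 or 1 read. Tie1, Erg, Cldn5 and Emcn had 0 reads in all 6 libraries, which allows up to 3 reads or between 1.64e-05% and 1.99e-05% of a library, for counting error only. Kdr, the main VEGF receptor, had 9 to 22 reads, and Sox18 had 11 to 24 reads. Of 12 endothelial genes, 0 reached 1 FPKM in any library, whereas the median of 8 fibroblast and collagen genes lay between 18.9 and 22.0 FPKM. Of the fixed list of fibroblast and mural cell markers, 7 of 17 members reached the filter on low values. Of the fixed endothelial and lymphatic lists, 9 of 37 and 5 of 11 members did. In the controls these included Pdpn, a lymphatic marker that fibroblasts also express, at 119 ± 6.0 FPKM (SD, n = 3), Flt4, the VEGF receptor gene of lymphatic endothelium, at 11.2 ± 0.63, Flt1 at 2.60 ± 0.23 and Fli1 at 2.25 ± 0.033. The leukocyte gene Ptprc had 0 reads in all 6 libraries, and the epithelial gene Epcam had at most 2. Of the fixed lists, 2 of 16 leukocyte and 2 of 12 epithelial members reached the filter on low values. In the controls the leukocyte marker Cd14 had 5.44 ± 0.59 FPKM and the epithelial marker Krt8 had 3.82 ± 0.21 FPKM (SD, n = 3).

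**Figure D1:**
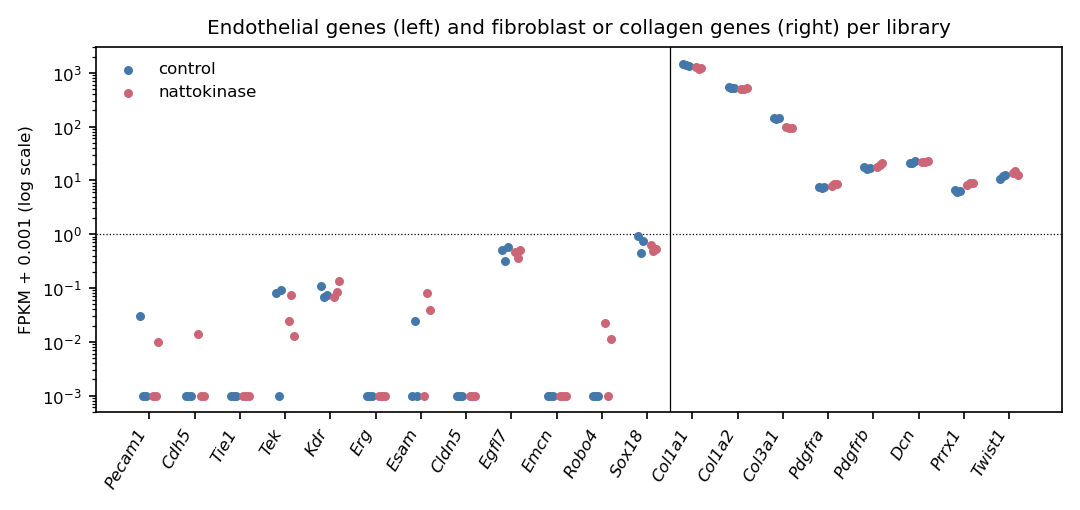
Deposited FPKM plus 0.001 on a log axis for 12 endothelial genes (left of the vertical line) and 8 fibroblast or collagen genes (right), with 1 point per library, control in blue and nattokinase in red; the dotted line marks 1 FPKM. Every endothelial gene lies below 1 FPKM in each of the 6 libraries, and Col1a1 averages 1319 FPKM.

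Nattokinase-treated cells held more mRNA of Ccn2, Ankrd1, Thbs1 and Cyp26b1, and less of Dhrs3. Ccn2, the connective tissue growth factor gene, rose 2.48-fold from 187 ± 7.55 to 465 ± 3.19 FPKM (SD, n = 3 per group; chromosome 10, 24595442 to 24598683, GRCm38). Ankrd1, a nuclear ankyrin-repeat protein gene induced by mechanical load, rose 2.65-fold from 20.2 ± 0.54 to 53.4 ± 2.16 FPKM (chromosome 19, 36111961 to 36120099). Thbs1, the thrombospondin-1 gene, rose 2.37-fold from 155 ± 3.92 to 366 ± 38.4 FPKM (chromosome 2, 118111876 to 118127133). The steepest relative rise among the genes named by rule belonged to Cyp26b1, which encodes a retinoic acid hydroxylase, at 4.18-fold from 0.386 ± 0.060 to 1.61 ± 0.29 FPKM. Dhrs3, which encodes a retinaldehyde reductase, fell to 0.267 of its control level, from 21.02 ± 0.15 to 5.62 ± 0.27 FPKM (chromosome 4, 144892827 to 144928209; limma adjusted p = 1.9e-07).

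Of 10913 genes tested with limma, 612 were higher and 354 lower with nattokinase at a Benjamini-Hochberg adjusted p of 0.05, which is 8.85% of those tested. Changes were mostly small, with 61 of the higher and 44 of the lower genes at 1.5-fold or more on the log2(FPKM + 1) scale, and 12 and 11 at 2-fold or more. Among the 11 were the 6 rRNA-like genes described below, at −2.14 to −2.05 on the log2 scale, and Rn7sk at −1.32. These genes were singled out after their values were seen, and whether their fall reflects the cells or the libraries stays open. In each of the 966 called genes all 3 nattokinase libraries lay on one side of all 3 controls, which largely follows from the call with 3 libraries per group. Such separation held for 28.8% of all tested genes, the called ones included, where chance gives 10%. Among the 12 genes with the highest log2 fold change that met the rule for naming were Mgp, Ankrd1, Ccn2, Thbs1, Spp1, Ccl7, Ccl2, Acta2, Actg2, Sgk1 and Cyp26b1. Their log2 fold changes ran from 1.44 for Mgp, an inhibitor of calcification, to 0.91 for Cyp26b1. Spp1, which encodes osteopontin, reached 170 ± 1.18 FPKM from 77.0 ± 3.04, and the kinase gene Sgk1 reached 24.5 ± 1.88 from 12.3 ± 1.24. The 12 lower genes named by the same rule were Lars2, Dhrs3, Rtn4rl2, Hist1h1e, Il33, Tgm2, Lrrn4, Ogn, Zbp1, Serpinb1a, Igfbp3 and Vcan, with log2 fold changes from −2.07 to −0.69. The alarmin gene Il33 fell from 13.8 ± 0.30 to 7.44 ± 0.45 FPKM, and Ogn, which encodes the small proteoglycan osteoglycin, fell by 0.74 on the log2 scale. The call of Hist1h1e was lost without any 1 library other than control replicate 3 (adjusted p up to 0.11), and Hist1h1e is a linker histone with close paralogs.

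**Figure D2:**
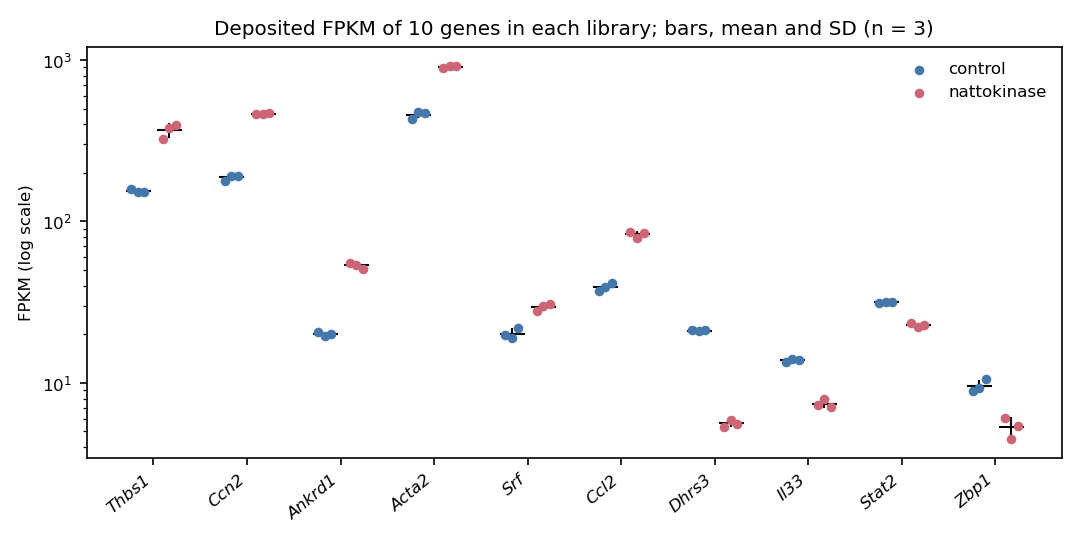
Deposited FPKM (log axis) of 10 genes in each library, with control in blue, nattokinase in red, and black bars for the mean and SD of 3 libraries. The nattokinase points lie above all control points from Thbs1 to Ccl2 and below them from Dhrs3 to Zbp1.

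The share of reads on rRNA-like transcripts differed between the groups. A set of 6 such genes, chosen after their values were seen and led by the 18S-like gene CT010467.1, took 3.35% ± 0.73 of assigned reads in the controls and 0.763% ± 0.051 in the nattokinase libraries (SD, n = 3 each). The controls held 3.98%, 3.52% and 2.55%, and the nattokinase libraries 0.734%, 0.822% and 0.732%. Lars2, a mitochondrial leucyl-tRNA synthetase gene that is annotated as protein coding and was counted in this set after it was seen to fall with the others, had a log2 fold change of −2.07, beside −2.12 for CT010467.1. Protein-coding genes took 95.99% ± 0.66 and 98.35% ± 0.044 of the reads. When FPKM were rescaled to equal totals on protein-coding genes, a choice made after seeing the data, 478 genes were higher and 497 lower, so that 49.0% of calls were higher against 63.4% with the values as deposited. The counts also moved with single libraries. They were 360 higher and 200 lower without control replicate 2, 409 and 209 without control replicate 3, 328 and 198 without nattokinase replicate 2, and 344 and 197 without nattokinase replicate 3. Without any filter on low values 221 and 109 genes passed, and 12 and 5 passed a test against a 1.5-fold change.

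Targets of SRF, the transcription factor that with its MRTF cofactors drives actin and contractile genes, rose as a group. Of 22 measured members of this list 20 rose and 0 fell (21 and 0 adjusted over the list alone). Acta2, which encodes smooth muscle actin, rose from 459 ± 23.1 to 907 ± 14.1 FPKM (log2 fold change 0.98, SE 0.054; chromosome 19, 34241090 to 34255590). The calponin gene Cnn2 had a log2 fold change of 0.57, the caldesmon gene Cald1 of 0.42, and the transgelin gene Tagln, expressed at low level here, of 0.70. Srf itself rose 1.46-fold from 20.2 ± 1.56 to 29.5 ± 1.47 FPKM (log2 fold change 0.53, SE 0.062, limma adjusted p = 0.00074; chromosome 17, 46548329 to 46556175). Camera gave the list an adjusted p of 2.5e-19 at its preset correlation, and the adjusted p was 0.090 with an estimated correlation. Fry, which asks only whether the members move one way on balance, gave 0.00052.

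Most immediate-early genes rose, as did 7 of 16 YAP targets. Among 24 immediate-early genes, whose transcripts respond within minutes to growth factors and stress, 17 rose and 0 fell (18 and 1 adjusted over the list alone; camera adjusted p = 1.6e-12, and adjusted p = 0.11 with an estimated correlation). The phosphatase gene Dusp1 rose from 11.9 ± 0.96 to 21.2 ± 1.5 FPKM, Egr1 from 34.8 ± 2.0 to 51.1 ± 2.0, and Nr4a1 and Klf6 had log2 fold changes of 0.70 and 0.55. Among 16 targets of the mechanosensitive coactivators YAP and TAZ, 7 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 8.6e-07, and adjusted p = 0.095 with an estimated correlation). Ankrd1 and Ccn2 led this list, followed by Ccn1, which rose from 175 ± 5.3 to 322 ± 8.2 FPKM, and Amotl2 with a log2 fold change of 0.29. The libraries with the higher levels of these lists were also those with the smaller rRNA-like share. Without control replicate 1, which stood apart on the second principal component, 21 SRF targets, 15 immediate-early genes and 8 YAP targets rose. Without nattokinase replicate 3 these counts were 17, 12 and 6, the lowest over the left-out libraries. Without the filter on low values 9 immediate-early genes rose.

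**Figure D3:**
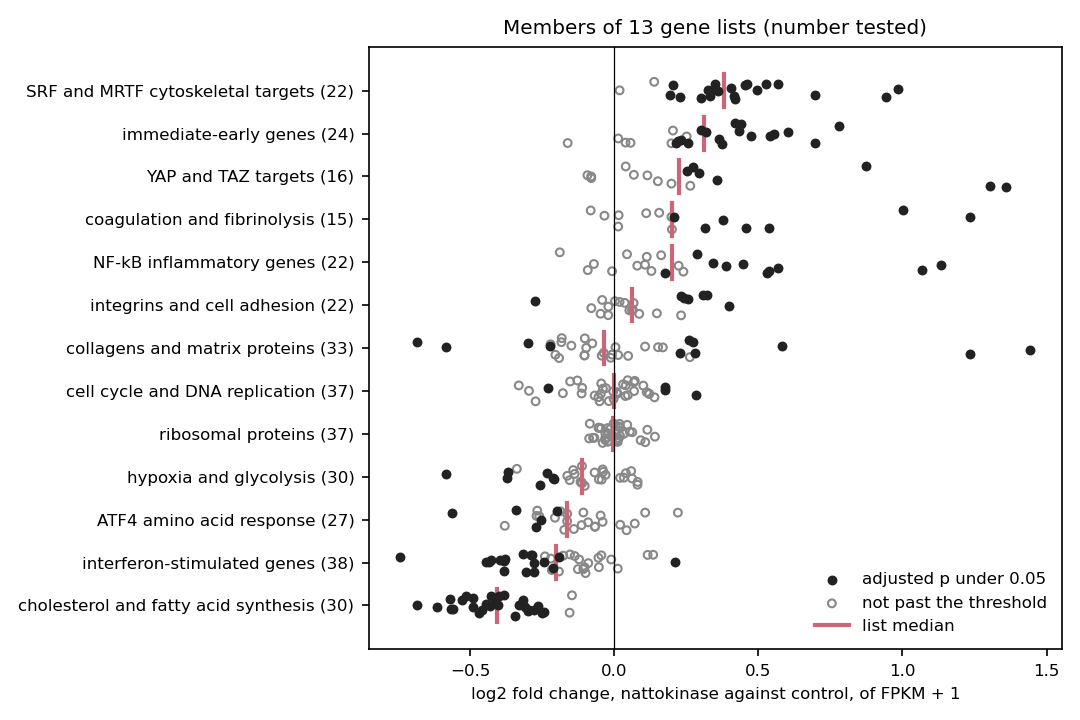
Log2 fold change of FPKM + 1, nattokinase against control, for each tested member of 13 gene lists (number tested in brackets); filled points have an adjusted p under 0.05, open points do not, and red bars are list medians. The medians run from 0.38 for SRF and MRTF targets to −0.41 for cholesterol and fatty acid synthesis.

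No list called by camera at its preset correlation was called with an estimated correlation, where 0 of 27 lists passed and 9 had an unadjusted p under 0.05. The preset test called 13 of the 27 lists in the real comparison and as many as 12 when the 6 libraries were regrouped across treatments. Each regrouping still set mostly control against mostly treated libraries and so kept part of the group difference. It therefore does not show how many lists would be called without one. Fry called 17 lists. The member counts come from the gene-wise limma test and do not rest on either correlation. Members of a list can move together across the same 6 libraries, so a count is not a number of independent results. A few genes belong to more than 1 list, among them Thbs1.

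Genes of coagulation and fibrinolysis, the process in which nattokinase acts as an enzyme, were partly higher. Of 15 measured members 7 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 1.2e-06, and adjusted p = 0.14 with an estimated correlation). Thbs1 was among those that rose. The thrombin receptor gene F2r rose from 162 ± 2.9 to 236 ± 12 FPKM, and Pdgfb had a log2 fold change of 0.46. Plau, the urokinase gene, rose 1.26-fold from 17.95 ± 0.90 to 22.6 ± 1.5 FPKM (limma adjusted p = 0.0088). Plat, which encodes tissue plasminogen activator, had 13.04 ± 0.086 FPKM in the controls and 12.7 ± 0.45 with nattokinase (limma adjusted p = 0.74).

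NF-kB target genes, a set of inflammatory genes, also shifted upwards. Of 22 measured members 10 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 9.3e-08, and adjusted p = 0.090 with an estimated correlation). The monocyte chemokine genes Ccl2 and Ccl7 led the list. Ccl2 rose 2.12-fold from 39.3 ± 2.26 to 83.4 ± 3.52 FPKM (chromosome 11, 82035571 to 82037453), and Ccl7 rose 2.24-fold from 25.4 ± 2.23 to 56.7 ± 1.91. Vcam1, a leukocyte adhesion molecule gene, rose 1.47-fold from 15.6 ± 0.45 to 23.0 ± 0.90 FPKM, and the inhibitor gene Nfkbie had a log2 fold change of 0.54. Icam1 was not tested, with 5 to 17 reads per library and means of 0.130 and 0.162 FPKM in control and treated cells. Without the filter on low values 6 members of this list rose.

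Cholesterol and fatty acid synthesis genes were lower almost throughout. Of 30 measured members 28 fell and 0 rose (30 and 0 adjusted over the list alone), with a median log2 fold change of −0.41. The mevalonate kinase gene Mvk fell from 15.9 ± 0.73 to 11.2 ± 0.68 FPKM, and the desaturase genes Fads2 and Scd2 fell from 208 ± 3.7 to 154 ± 3.1 and from 281 ± 3.3 to 197 ± 18 FPKM. Camera gave an adjusted p of 1.9e-28, and the adjusted p was 0.11 with an estimated correlation. Without control replicate 1, 25 members fell, and without the filter on low values 12 did. The lowest count over the left-out libraries was 22, without nattokinase replicate 2. As with the lists that rose, the rRNA-like share differed between the groups in the same libraries.

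Interferon-stimulated genes were lower in part. Of 38 measured members 17 fell and 1 rose (23 and 1 adjusted over the list alone; camera adjusted p = 8.7e-14, and adjusted p = 0.14 with an estimated correlation). Stat2, a transcription factor of type I interferon signalling, fell from 31.5 ± 0.10 to 22.9 ± 0.66 FPKM. Oasl2 fell from 44.8 ± 0.71 to 34.1 ± 0.45, the nucleic acid sensor gene Zbp1 from 9.57 ± 0.86 to 5.34 ± 0.80, and the antigen transporter gene Tap1 had a log2 fold change of −0.40. The count that fell was 22 without control replicate 1, 11 without nattokinase replicate 3 and 6 without the filter on low values. The member that rose, Irgm1, was singled out after its value was seen, and its log2 fold change of 0.21 lost its call after rescaling to protein-coding totals (adjusted p = 0.051) and without control replicate 2 or any nattokinase replicate (adjusted p up to 0.12).

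Smaller shifts were seen in lists of amino acid stress, hypoxia and protein folding. Of 27 ATF4 target genes 5 fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 2.6e-06, and adjusted p = 0.30 with an estimated correlation). Fry did not call this list (fry adjusted p = 0.097). The pseudokinase gene Trib3 fell from 27.2 ± 2.3 to 18.1 ± 1.6 FPKM, and Wars, a tryptophanyl-tRNA synthetase gene, had a log2 fold change of −0.34. The number of ATF4 targets that fell was 8 without control replicate 1, 2 without control replicate 2, 3 without control replicate 3, 12 without nattokinase replicate 1, and 2 without nattokinase replicate 2 or 3. Of 30 hypoxia and glycolysis genes 7 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 2.0e-05, and adjusted p = 0.23 with an estimated correlation), including Pfkfb3 at −0.37 and Car9 at −0.58 on the log2 scale. Here 12 fell without control replicate 1, 3 without control replicate 2 or 3 or nattokinase replicate 2, and 2 without nattokinase replicate 3. Without the filter on low values 1 gene of each of these 2 lists fell, and over all libraries 9 ATF4 targets fell with limma-voom and 13 hypoxia genes with quantile normalization. Of 22 genes of the unfolded protein response 1 rose and 2 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.0017, and adjusted p = 0.23 with an estimated correlation). Atf6, a sensor of the endoplasmic reticulum, rose by 0.29 on the log2 scale, and Hyou1 and Sdf2l1 had −0.19 and −0.24. The calls of Hyou1 and Sdf2l1 were both lost without control replicate 2 or 3 or nattokinase replicate 2 or 3, with adjusted p up to 0.12 and 0.11, and that of Sdf2l1 also without nattokinase replicate 1. The number of unfolded protein response genes that fell was 5 without control replicate 1, 1 without nattokinase replicate 1 and 0 without any other library.

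Few of the endothelial genes could be tested. Only 9 of 37 listed genes reached the filter, of which 2 rose and 0 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.063, and adjusted p = 0.23 with an estimated correlation). Fry called the list higher (adjusted p = 0.0011). Flt1, a VEGF receptor gene, rose from 2.60 ± 0.23 to 4.84 ± 0.21 FPKM, and the flow-responsive transcription factor gene Klf2 from 3.22 ± 0.59 to 5.69 ± 0.24. Nos3, the endothelial nitric oxide synthase gene, had 0 to 4 reads per library and was not tested. Of 5 lymphatic markers 1 fell, the podoplanin gene Pdpn at 119 ± 6.0 and 102 ± 2.7 FPKM (camera adjusted p = 0.070 for the list, and adjusted p = 0.23 with an estimated correlation). Camera called the lymphatic list lower without control replicate 2 (adjusted p = 0.031) and, over all libraries, with the gene length and GC correction (adjusted p = 0.0497), as fry did (adjusted p = 0.031). The call of Pdpn was lost without any 1 library other than control replicate 1 (adjusted p up to 0.10). Among 7 markers of fibroblasts and mural cells 1 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.052), namely the mesenchymal transcription factor gene Prrx1 with a log2 fold change of 0.41. Camera called this list higher without control replicate 3 (adjusted p = 0.0495) or nattokinase replicate 1 (adjusted p = 0.029) and with quantile normalization (adjusted p = 0.049), fry called it (adjusted p = 0.012), and its camera adjusted p over all libraries was 0.28 with an estimated correlation. Of 2 measurable leukocyte markers Cd68, a lysosomal gene, rose from 1.19 ± 0.33 to 2.42 ± 0.35 FPKM, and neither of 2 measurable epithelial markers passed the test (camera adjusted p = 0.13 and 0.70 for these lists, and fry adjusted p = 0.031 for the former).

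Matrix, adhesion and protease genes went both ways. Of 33 collagens and matrix proteins 7 rose and 4 fell (10 and 9 adjusted over the list alone; camera adjusted p = 0.52), and the list's median log2 fold change of −0.04 and its mean of 0.05 differed in sign. Thbs1 and Mgp were among those that rose, whereas the type III collagen gene Col3a1 fell from 144 ± 2.6 to 95.8 ± 1.1 FPKM and the proteoglycan gene Vcan from 6.29 ± 0.88 to 3.52 ± 0.33. The counts that rose and fell were 3 and 2 without control replicate 2, 4 and 3 without control replicate 3, 3 and 3 without nattokinase replicate 2, and 4 and 4 without nattokinase replicate 3. Of 22 integrins and adhesion genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.022, and adjusted p = 0.14 with an estimated correlation), among them Mcam at 0.40, Cd9 at 0.32 and the N-cadherin gene Cdh2 at 0.31 on the log2 scale. Of 30 matrix proteases and inhibitors 6 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.022, and adjusted p = 0.28 with an estimated correlation). Adamts1 rose from 16.8 ± 0.31 to 27.1 ± 2.4 FPKM and Adam12 by 0.62 on the log2 scale, and the matrix metalloproteinase genes Mmp13 and Mmp3 had −0.44 and −0.68. Without nattokinase replicate 3 the camera calls of the adhesion and protease lists were lost (adjusted p = 0.053 and 0.063). Without control replicate 2, 3 adhesion genes rose and 0 fell, and without nattokinase replicate 3, 3 protease genes rose. With limma-voom 11 protease genes rose, and 10 matrix genes rose and 8 fell. Of 17 targets of BMP, TGF-beta and Notch signalling 5 rose and 3 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.19, fry adjusted p = 0.0015). The activin subunit gene Inhba rose from 11.7 ± 1.2 to 21.7 ± 0.74 FPKM, Ltbp2 and Tgfb2 had log2 fold changes of 0.65 and 0.27, and the BMP-responsive gene Atoh8 fell by 0.57. The count of this list that fell was 1 without control replicate 2 or 3 or nattokinase replicate 2 or 3.

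Genes of proliferation, survival and protein synthesis showed few calls. Of 37 cell cycle genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.52), with Cdc20 at −0.23 and Mcm4 at 0.18 on the log2 scale. The 3 rises were not robust, since 0 members rose without control replicate 2 or 3 or nattokinase replicate 1 or 2, 1 rose without nattokinase replicate 3, and 0 rose after rescaling to protein-coding totals, and the call of Cdc20 was lost without nattokinase replicate 2 (adjusted p = 0.053). The count that fell was 3 without control replicate 1 or with protein-coding totals, and 4 with quantile normalization or the gene length and GC correction. Of 24 p53 targets 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.52), the latter being Sesn1 at −0.38. The former, Casp8, had 0.21 and lost its call without any 1 library other than control replicate 1 (adjusted p up to 0.073). Of 19 heat shock genes 2 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.067), led by Dnajb4 with a log2 fold change of 0.41, and the list was called without control replicate 3 (adjusted p = 0.029) or nattokinase replicate 2 (adjusted p = 0.043). Over all libraries it was also called with no filter on low values (adjusted p = 0.014) and with the gene length and GC correction (adjusted p = 0.0497), although the adjusted p was 0.56 with an estimated correlation, and 5 rose with limma-voom. Of the heat shock genes 3 rose without control replicate 1 or 3, and 1 without control replicate 2 or any nattokinase replicate. Fry did not call the heat shock list (fry adjusted p = 0.088). Of 37 ribosomal protein genes 0 passed by limma and 0 by limma-voom, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.56), but the list was called lower without control replicate 1 (adjusted p = 5.3e-05). Over all libraries its adjusted p was 0.91 with an estimated correlation. Of 12 mitochondrially encoded mRNA genes 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.16), and the list was called higher without control replicate 1 (adjusted p = 0.047), where 2 rose. Over all libraries it was called higher with quantile normalization (adjusted p = 0.0028), where 3 rose. The list's adjusted p over all libraries was 0.58 with an estimated correlation and 0.13 with fry, and 4 members rose with limma-voom. The gene that rose, mt-Nd2, had a log2 fold change of 0.23 and lost its call after rescaling to protein-coding totals (adjusted p = 0.054) and without control replicate 2 or any nattokinase replicate (adjusted p up to 0.17). Of 4 measurable metallothionein and zinc transport genes 0 passed by limma and 0 by limma-voom, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.52). Of 25 NRF2 genes 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.052), with the heme oxygenase gene Hmox1 at 0.31 and the peroxidase gene Gpx1 at −0.36 on the log2 scale. The list was called lower without control replicate 1 (adjusted p = 0.0042), where 4 members fell, and 1 fell without any other library. Over all libraries the list had an adjusted p of 0.56 with an estimated correlation and 0.39 with fry. It was also called lower over all libraries with median-of-ratios scaling (adjusted p = 0.035), protein-coding totals (adjusted p = 0.027), quantile normalization (adjusted p = 0.022) and the gene length and GC correction (adjusted p = 0.020), and the count that fell was between 0 without the filter and 5 with quantile normalization. Of 6 tested members of the list of replication-dependent histones 3 fell and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.00012, and adjusted p = 0.098 with an estimated correlation), led by Hist1h1b at −0.92 on the log2 scale. The list missed many measurable histones, and among all 17 tested genes named after the histone clusters, a set formed after the data were seen with 1 annotated pseudogene, the same 3 fell and 0 rose. Most transcripts of such genes lack a poly(A) tail, as rRNA does, but the list also held H1f0, whose mRNA is polyadenylated. Of the list 1 fell without control replicate 2 or nattokinase replicate 2, 2 without control replicate 1 or nattokinase replicate 1 or 3, and 0 of 19 without the filter on low values.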

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

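Pseudocounts of 0.1 and 0.5, quantile normalization, protein-coding totals and the gene length and GC correction were chosen after seeing the data. No gene called higher or lower was called in the opposite direction under any of the 17 other settings. Of the 612 higher and 354 lower genes, 592 and 329 were shared with limma-voom on recovered reads, which called 870 and 464. Without the filter on low values, over 24549 genes, 221 were higher and 109 lower. A test against a 1.5-fold change left 12 and 5, as a stricter question does. Without 1 library, and so with fewer samples, the counts ranged from 328 to 720 higher and from 197 to 486 lower. Camera called 13 lists, 11 to 16 under other settings and 0 with an estimated correlation, and fry called 17. Of 85 named genes past the threshold, 74 passed without any 1 library and 11 lost the call without at least 1. The log2 fold change of Pltp, never called, was 0.020 without nattokinase replicate 1 and ran from −0.10 to 0.020 over the left-out libraries; the cause was not tested. The replicate numbers share only a number, since same-numbered libraries had deviations correlated at −0.089, −0.044 and −0.059 and did not correlate best with their own number. With the number as a replicate block 439 genes were higher and 249 lower. A Wald test with DESeq2 and the edgeR fits with TMM or other size factors were not run; limma-voom was the test run on the recovered reads. Library totals gave no other scaling, since FPKM are already scaled by them. Depth limits genes such as Icam1 and Nos3, with at most 17 and 4 reads per library.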

Other observations

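The tests of non-poly(A) RNA, of a shared rRNA factor, of a single deviating library and both tests on endothelial markers were chosen only after the results were seen, as were the genes of the next paragraph. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For genes, 1 split, the real one, reached 612 higher and 1 reached 354 lower, and the highest other count was 1. For lists, 1 split reached 13, and the highest other count was 12. The other splits mix the groups, which puts the group difference into the spread within groups and leaves part of it between them. Low gene counts in them would follow from any difference between the groups, and their list counts are not free of it. Neither comparison therefore weighs for or against an effect of nattokinase.

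Transcripts of the vasoconstrictor endothelin-1 and of a cholesterol exporter rose outside the fixed lists. Edn1 rose from 11.6 ± 0.37 to 20.2 ± 0.69 FPKM (SD, n = 3 each; log2 fold change 0.75, SE 0.049, limma adjusted p = 3.4e-05). Abca1, which moves cholesterol out of cells, rose from 3.91 ± 0.29 to 6.99 ± 0.66 FPKM (log2 fold change 0.70, limma adjusted p = 0.00050). In retinoid metabolism Dhrs3 and Cyp26b1 changed in opposite directions, at −1.74 and 0.91 on the log2 scale, in all 3 nattokinase libraries against all 3 controls. The retinoic acid receptor gene Rarg had a log2 fold change of −0.13 (limma adjusted p = 0.076).

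The rRNA-like share was 3.35% in the controls and 0.763% with nattokinase. Less carry-over of RNA without a poly(A) tail would lower other such transcripts too, and Rn7sk fell from 8.04 ± 2.11 to 2.59 ± 0.57 FPKM (limma adjusted p = 0.013, up to 0.066 without control replicate 2, and also lost without nattokinase replicate 1), as did Hist1h1b and Hist1h1e. Over 82 such genes the median log2 fold change was −0.14, with 50 below 0, 4 called lower and 2 called higher. Its 95% bootstrap interval, over genes and not libraries, was −0.25 to −0.005, and the median log2 ratio of mean FPKM was −0.21. The 17 histone genes had a median of −0.25. The 64 snRNA, snoRNA and scaRNA genes, short RNAs of the nucleus, had a median of −0.06, with 34 below 0. Most of the 82 genes lie at low levels, where log2(FPKM + 1) shrinks a change, and short RNAs may be lost in library preparation. A difference in selection and a lower rRNA content of treated cells thus cannot be told apart. The 6 genes lay within 0.071 of the log2 fold change of CT010467.1, but they were picked because they fell, so this is no independent sign of 1 shared factor.

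A candidate explanation for the SRF, YAP, immediate-early and sterol lists is a response of the cells to nattokinase, which no value here tests apart from handling that went with the groups. Against a bias of gene length or GC content, at least 93.5% of each list's median fold change was kept after the correction. Against 1 deviating library, at least 81.0% of each list's median was kept without any 1 of the 6 libraries. Handling marked by the rRNA-like reads stays open. On the log2 scale, control replicates 3 and 1 differ by 30.4% of the group difference in these reads. Between them the immediate-early list moved by 44.0% of its effect and the SRF list by 15.2%, but the YAP and sterol lists by −4.4% and 1.6%, and these are single libraries.

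A sterol load might lower the sterol genes and, sensed by LXR, raise Abca1. The other 4 measured LXR targets, however, had a median of −0.13 and went both ways (Arl4c 0.30, Pltp −0.05, Lpcat3 −0.22 and Lpl −0.34). Camera at its preset correlation did not call them (limma's camera, p = 0.16), and so few members moving apart decide nothing.

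A set of 12 common endothelial genes was near 0 in a line labelled endothelial, while Flt4 (11.2 ± 0.63 FPKM in the controls) and some other endothelial or lymphatic genes were expressed. A minority of fibroblasts in an endothelial culture would leave those 12 genes abundant, and the highest library median of 12 of them was 0.0095 FPKM. These 12 were chosen after their values were seen, and of the 37 endothelial genes fixed beforehand 9 reached the filter on low values. Of 17 fibroblast and mural cell markers fixed beforehand 7 did. Loss of part of the endothelial expression in the line and another line under its name may both give 0 of 12 genes at 1 FPKM, and these libraries cannot tell them apart; a genotype of the cells would. No biological explanation that the design names was tested for this pattern, which is shared by both groups.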
